A study of Acanthocheilonema viteae with 2 samples.

How the data were processed

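Small RNA released by adult Acanthocheilonema viteae into culture medium was sequenced in 2 samples, 1 library from females and 1 from males. Per the labels' protocols, the sexes were kept apart in culture for up to 3 weeks in RPMI medium with antibiotics and glutamine. The collected medium was cleared of debris, sterile filtered, frozen, concentrated and ultracentrifuged, so that the RNA came from the washed high-speed pellet, the fraction that holds extracellular vesicles and other large particles. Total RNA was extracted with a column kit and libraries were made with the Illumina TruSeq small RNA chemistry, per the labels' protocols. The aligner, the miRNA database release and the genome used by the authors are not given in the sources used here.

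The authors deposited a table of 384 entries, each with a miRNA name, a mature sequence of 18 to 26 nt, a raw column and a normalized column per library. Per the file headers and the values, the raw column holds estimated counts: 78 sequences stood on more than 1 entry (159 entries), the entries of each such sequence held equal values, and 126 entries held parts of reads, 11 of them on sequences that were not repeated. The authors therefore appear to have divided reads between names that share them. The deposited normalized column, treated here as a signal, equalled the raw column times a constant per library, 1.09 for the female and 0.915 for the male library, with a product of 1; how the authors chose these constants is not given in the sources used here. No entry was at 0 in both libraries, and the smallest sum of reads of any sequence over both libraries was 3.5, so a minimum may have been applied before deposit. Columns of per-sample values that were left unused numbered 0. The expected counts were rounded to whole numbers for intervals and for edgeR, and kept as deposited elsewhere.

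Entry names carry miRBase species codes. They were sorted into nematode-named entries (86), mammal-named entries (255) and predicted candidates without a species (43, names starting with PC). A name says which known miRNA a sequence resembles and is no proof of origin: the sequence under the Ascaris name asu-let-7-5p is also that of mammalian let-7a, and the sequences under the nematode names for miR-1, miR-100b and miR-124 begin like their mammalian counterparts. Suffixes such as _R+1 or _1ss20GA are kept as deposited. No reference genome was used, so no coordinates are given.

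The main scale was the share of all reads of a library, summed over the deposited entries. Ratios compare the shares of the 2 libraries, with an exact conditional binomial (Clopper-Pearson) 95% interval, and shares carry an exact binomial (Clopper-Pearson) 95% interval. An entry at 0 in a library was set to a floor of 3 reads. Its ratio is then a value against that floor, and the lower end of its 95% interval lies below that value. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. With 1 library per sex there is no replicate spread and no test between the sexes. Entries were called by size, with a share at least 2 times higher in a library, among entries with at least 10 reads in at least 1 library. The entries named are the 10 most abundant of each library, the 10 largest ratios in each direction, and members of 20 lists of miRNA families and tissue miRNAs. For each list the summed shares were compared, and for lists with at least 3 eligible entries the median log2 ratio was placed among 10000 random lists of the same size matched on mean abundance. Pearson and Spearman correlations across entries used log2 shares with 0.5 reads added.

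The groups, the scale, the size rule, the naming rule, the lists and most alternatives were fixed before the data were examined. The alternatives were median-of-ratios scaling, edgeR TMM scaling, totals without the most abundant single entry of each library and the authors' normalized values. Further ones were other read minimums, merging of identical sequences, grouping by seed (nucleotides 2 to 8), thinning of the female library and intervals beyond the size rule. The pseudocount alternatives did not apply because counts were deposited. The sorting by species code, the scale of nematode-named plus candidate reads, the comparison of candidates with known miRNAs and 4 further lists of mammalian miRNAs were chosen after seeing the data.

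Over the deposited entries the female library held 292740 reads and the male library 74881.3. On this scale 3 reads equal 0.00102% of the female and 0.00401% of the male library. The rule was tested on simulated data for this comparison of 384 entries in 50 draws, with 60 entries changed 4-fold. Of the changed entries 95.5% were called in their own direction, and of the unchanged entries 11.9% were called. Shares were rescaled to their new total after the change, so the calls of unchanged entries mix counting noise with that shift. The true ratio, with the shift included, lay in 96.4% of the intervals. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 (TMM factors) and RNAduplex of ViennaRNA 2.7.2.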

Results

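The miRNAs that adult worms of Acanthocheilonema viteae, a filarial nematode of rodents, release into culture medium were profiled to compare females with males. There was 1 library of female and 1 of male secretions, with 292740 and 74881.3 reads summed over the deposited entries, 3.91 times as many in the female. Totals of sequenced reads were not used, so sequencing depth was not compared. Because no library was replicated, every ratio here compares these 2 libraries and not the sexes, and intervals give counting error only.

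Female secretions were dominated by nematode miRNAs, whereas male secretions held about as many reads of mammal-named as of worm miRNAs. Nematode-named entries took 87.4% of the female reads (95% interval 87.3 to 87.5) and 44.2% of the male reads (43.9 to 44.6). Predicted candidates took 5.88% and 4.36%. Mammal-named entries took 6.71% of the female reads (6.62 to 6.80) and 51.4% of the male reads (51.1 to 51.8). Mammalian miR-21, abundant in many mammalian tissues, made up 1.08% of the female and 11.1% of the male library over its 2 entries, 10.3-fold higher in the male (9.92 to 10.8). A list of mammalian liver, blood, gut and smooth muscle miRNAs, fixed in advance as a marker of other sources of RNA, took 1.44% of the female and 14.2% of the male reads, with 9 of its 11 eligible entries at least 2-fold higher in the male library and none in the female. The list includes miR-21, so its sum is no separate evidence. Of its 4215 female and 10596 male reads, these 2 miR-21 entries held 3156 and 8346, and miR-143 held 716 and 1633. In raw reads, which were 3.91 times fewer in all, the male library still held more mammal-named reads (38510.3 against 19634) but fewer nematode-named reads (33106 against 255906).

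**Figure D1:**
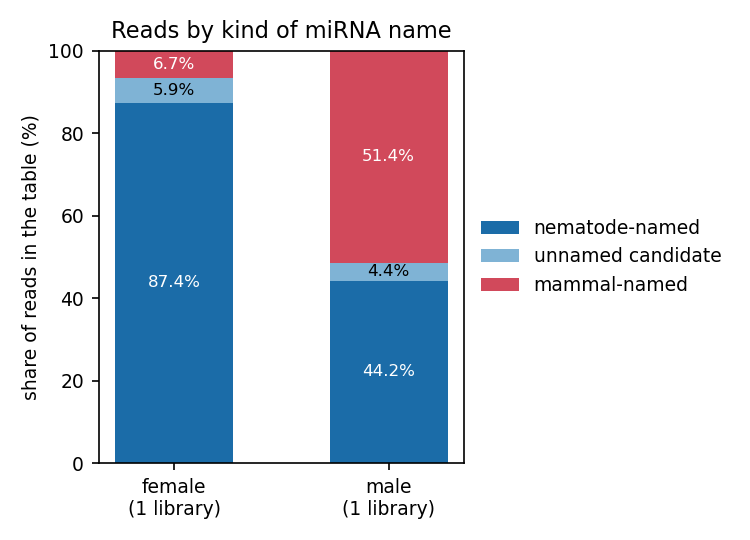
Share of reads (%) by kind of miRNA name in the female and the male library, 1 library each, with bars stacked to 100%. Mammal-named entries made up 6.71% of the female and 51.4% of the male reads, and nematode-named entries 87.4% and 44.2%.

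This difference in makeup sets the scale of every other ratio. On the scale of nematode-named plus candidate reads, called worm reads below, each female-to-male ratio is 1.92 times lower than on the scale of all reads, and on the authors' normalized values it is 4.67 times higher. Both share scales are therefore given for most worm miRNAs. Over all 287 eligible entries, 53 were at least 2-fold higher in the female and 178 in the male library (22.9% of calls female), against 114 and 87 (56.7% female) on the authors' normalized values. Of the 112 eligible nematode-named and candidate entries, 40 were at least 2-fold higher in the female and 21 in the male library, against 9 and 38 on the scale of worm reads and 96 and 6 on the authors' values. Of the 175 eligible mammal-named entries, 157 were at least 2-fold higher in the male and 13 in the female library, against 81 and 18 on the authors' values. The median mammal-named entry seen in both libraries was 9.06-fold higher in the male library, and 1.94-fold higher on the authors' values.

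The worm part of both libraries was led by the miR-100 and miR-36 families. The nematode-named members of the miR-100/miR-51 family, which acts in embryonic development of Caenorhabditis elegans, took 46.0% of all female and 15.4% of all male reads, a ratio of 2.99 (2.94 to 3.05). Among worm reads they took 49.3% and 31.6%, a ratio of 1.56 (1.53 to 1.59). The most abundant entries of the female library were bma-miR-100a_R+1 (AACCCGTAGTTTCGAACATGTGT), with 20.7% of reads against 6.64% in the male, and bma-miR-100d_R+1 (TACCCGTAGCTCCGAATATGTGT), with 19.2% against 5.91%. Their ratios were 3.12 (3.03 to 3.21) and 3.25 (3.15 to 3.35) over all reads, and 1.63 and 1.69 over worm reads. The entries bma-miR-100b_R+1 and bma-miR-100c_R+2_1ss12CT had ratios of 2.29 and 1.99 over all reads and 1.19 and 1.03 over worm reads. The sequence of bma-miR-100b_R+1 (10611 female and 1183 male reads) begins like mammalian miR-100, so its origin cannot be told from its name. All 3 entries of the miR-35/miR-36 family, which acts in oogenesis and the early embryo of C. elegans, were at least 2-fold higher in the female library, together 15.8% against 7.61% of reads and a ratio of 2.07 (2.02 to 2.13). Summed by name, this family was nearly level over worm reads, 16.9% against 15.7% and a ratio of 1.08 (1.05 to 1.11). The sum was carried by bma-miR-36c-3p_R-1_1ss20GA (TCACCGGAGACATTGTTCCAC), with 14.2% of female and 7.07% of male reads and a ratio of 2.01 (1.96 to 2.07). It was the most abundant single entry of the male library, where miR-21 over its 2 entries held more, 11.1%. With membership by seed, bma-miR-36c-3p_R-1_1ss20GA fell out of the family and only bma-miR-36a_R+1_1ss20TC stayed. That entry had a ratio of 2.87 over all reads and 1.49 over worm reads, so the near-level sum rests on name membership.

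**Figure D2:**
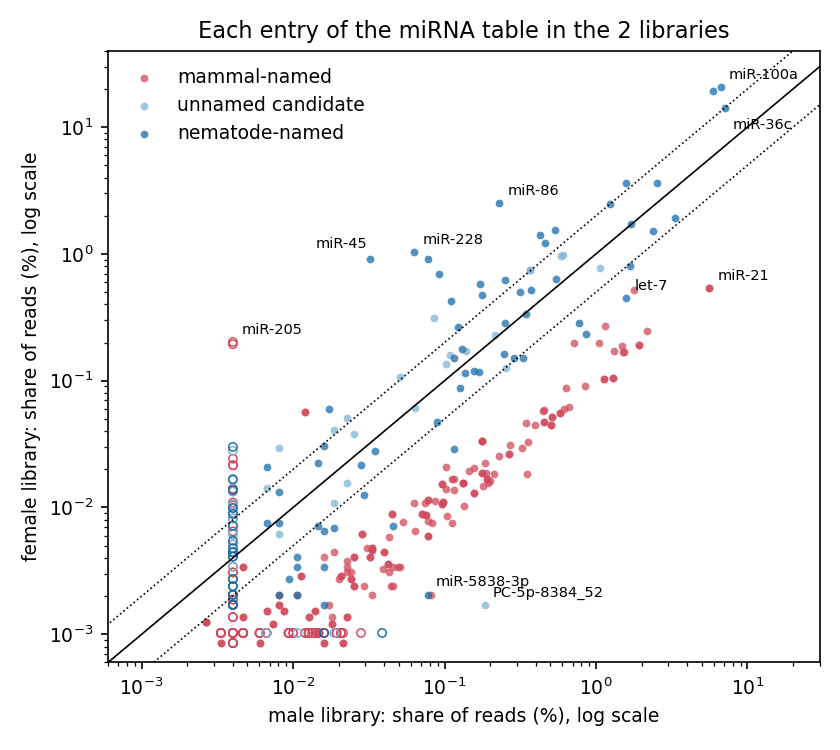
Each of the 384 entries by its share of reads (%) in the male library (horizontal, log scale) and the female library (vertical, log scale), coloured by kind of name, with open symbols for entries at 0 in a library drawn at the floor of 3 reads. The solid line marks equal shares and the dotted lines 2-fold differences; most mammal-named entries lie along a band with a median 9.06-fold higher in the male library, and miR-45, miR-228 and miR-86 lie above the upper dotted line.

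A small set of worm miRNAs was far higher in the female library on every scale used. The miRNA bma-miR-45 (CGACTAGAGGAACATTCAGCAT) had 2678 female and 24 male reads, a ratio of 28.5 (19.1 to 44.6) over all reads and 14.9 (9.97 to 23.2) over worm reads. The glial miRNA of C. elegans, miR-228, had 3005 and 47 reads and a ratio of 16.4 (12.3 to 22.3), or 8.51 over worm reads. For bma-miR-307_R-1 (2675 and 58 reads) the ratio was 11.8 (9.10 to 15.6), for asu-miR-86-5p (7339 and 172 reads) 10.9 (9.38 to 12.8), and for bma-miR-50 (2047 and 69 reads) 7.59 (5.97 to 9.79). Over worm reads these 3 ratios were 6.14, 5.68 and 3.95. Relative to the median of the worm entries seen in both libraries, which no scaling can move, miR-45 lay 23.2 times higher in the female library, miR-228 lay 13.3 times higher, miR-307 lay 9.57 times higher, miR-86 lay 8.86 times higher and miR-50 lay 6.16 times higher. The miRNA bma-miR-234_R+3 (88 reads) and the candidate PC-3p-6544_68 (82 reads) were read in the female library and at 0 in the male. Against the floor they were 7.50-fold and 6.99-fold higher over all reads (95% lower limits 5.98 and 5.56). Over worm reads they were 3.91-fold and 3.64-fold higher (lower limits 3.11 and 2.89). On the lists, the miR-228/miR-263 family had a ratio of 16.4 (8.53 over worm reads), miR-86 of 11.0 (5.70) and the nematode-named miR-50/miR-190 entries of 6.48 (3.37), where asu-miR-50-5p went the other way with 5 female and 12 male reads.

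The worm entries with the largest excess in the male library came at low abundance. The candidate PC-5p-8384_52 (TTTTGGTTGAACAGTTCTTGTTTT) had 138 male and 5 female reads, 108-fold higher in the male over all reads (45.1 to 338) and 207-fold over worm reads. Both arms of bma-miR-5838 were male-high. The 3p arm had 58 male and 6 female reads, 37.8-fold higher (16.3 to 107). The 5p arm had 29 male reads and 0 female reads, 37.8-fold higher against the floor (95% lower limit 28.8). Over worm reads each arm was 72.6-fold higher. These 3 entries kept their direction on every scale used.

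The nematode-named entries of the let-7, lin-4 and miR-2 families summed to more of the male library on both share scales, though not on the authors' normalized values. The 2 nematode-named entries of the let-7 family, which times larval development, were both at least 2-fold higher in the male library, 1.60% against 0.449% of reads, 3.56-fold over all reads and 6.84-fold over worm reads. Most of these reads came from asu-let-7-5p, whose sequence mammals share, with 1304 female and 1185 male reads. The 8 eligible mammal-named let-7 entries were also at least 2-fold higher in the male library, together 9.70-fold. The nematode lin-4, asu-lin-4-5p_1ss19TC, was 1.55-fold higher in the male over all reads (1.47 to 1.64) and 2.98-fold over worm reads, and the mammal-named miR-125 entries of that family 10.1-fold higher over all reads. The miR-2 family was 2.17-fold higher in the male over all reads and 4.17-fold over worm reads, with bma-miR-2c_R+1_1ss1CT and bma-miR-250_R-1_1ss20CT at least 2-fold higher in the male, and bma-miR-2a at a ratio of 1.37. Its median lay at percentile 3.12 of random worm lists and 65.8 of random lists over all entries. Of all the lists placed among random worm lists, it was the lowest and the neuronal list, at 93.0, the highest. The others lay from 11.4 to 84.6. With membership by seed (9 entries) the family was 1.44-fold higher in the male over all reads, under the size rule, and its median log2 ratio was 0.40, toward the female. On the authors' normalized values asu-let-7-5p, lin-4, miR-2c and miR-250 turned to the female side, with female-to-male ratios of 1.31, 3.01, 2.25 and 1.27.

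Neuronal miRNAs summed to more of the female library on every scale used, whereas the side of the muscle miRNAs depended on the scale. All 4 nematode-named entries of the neuronal list (miR-124 on 2 entries, miR-7 and miR-9) were at least 2-fold higher in the female library over all reads and none over worm reads, where their ratios ran from 1.13 to 1.79, with a summed ratio of 2.45 (2.17 to 2.77) over all reads and 1.27 (1.13 to 1.44) over worm reads. Their median lay at percentile 93.0 of random worm lists. The miR-9 entry is the 3p arm, bma-miR-9-3p, with 778 female and 92 male reads, and membership by seed leaves it out. By seed the 3 nematode-named entries summed to a ratio of 2.58 (2.23 to 2.99) over all reads and 1.34 (1.16 to 1.56) over worm reads. The main entry, bma-miR-124_R-1, had 1828 female and 187 male reads. With 3 mammal-named entries, which summed to a ratio of 0.834 (0.517 to 1.39), the list had 6 of 7 entries higher in the female. Its median then lay at percentile 99.5 of random lists over all entries, which are mostly mammal-named. The nematode-named muscle entries summed to a ratio of 1.12 (0.998 to 1.26), or 0.582 over worm reads, made up of asu-miR-1-3p_R-1 at 1.38 (0.721 over worm reads) and asu-miR-133-3p_R-1, 4.00-fold higher in the male (7.69-fold over worm reads). With the 2 mammal-named muscle entries the ratio was 1.11, and with membership by seed 1.41 (1.24 to 1.60).

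Most of the remaining lists lay within 2-fold over all reads, and most changed side with the scale. The bantam/miR-58 family, led by asu-miR-81a (3.64% of female and 2.52% of male reads), had a ratio of 1.38 over all reads and 0.718 over worm reads. For miR-71, a miRNA of ageing and stress in C. elegans, the shares were 1.75% in both libraries, with a ratio of 1.00 (0.942 to 1.06), or 0.521 over worm reads, and bma-miR-71_R+4 alone had 0.997. For miR-87 the ratio was 1.31, or 0.683 over worm reads, and with membership by seed, which adds bma-miR-5843_1ss11TC, it passed the size rule at 2.00 over all reads (1.85 to 2.17). The nematode-named miR-10/miR-57 entry had 1.15, or 0.599, and the nematode-named miR-34 entries 0.947, or 0.493, while miR-34 with its mammal-named entry had 0.740. The miR-44/miR-279 family held opposite members: bma-miR-279_R+1 was 1.73-fold higher in the male library over all reads (1.65 to 1.81) and 3.32-fold over worm reads, miR-45 was far higher in the female, and their sum had a ratio of 0.848, or 0.441 over worm reads. The nematode-named miR-92 entry was on the female side on both share scales, with a ratio of 2.65, or 1.38 over worm reads, and the miR-72 entry on the male side on both, with 0.527, or 0.274. The mammal-named entries of the miR-92, miR-72/miR-31 and miR-10 lists were 5.40-fold, 6.50-fold and 9.61-fold higher in the male library. The miR-46/miR-281 family had 6 female and 0 male reads, too few for a ratio.

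**Figure D3:**
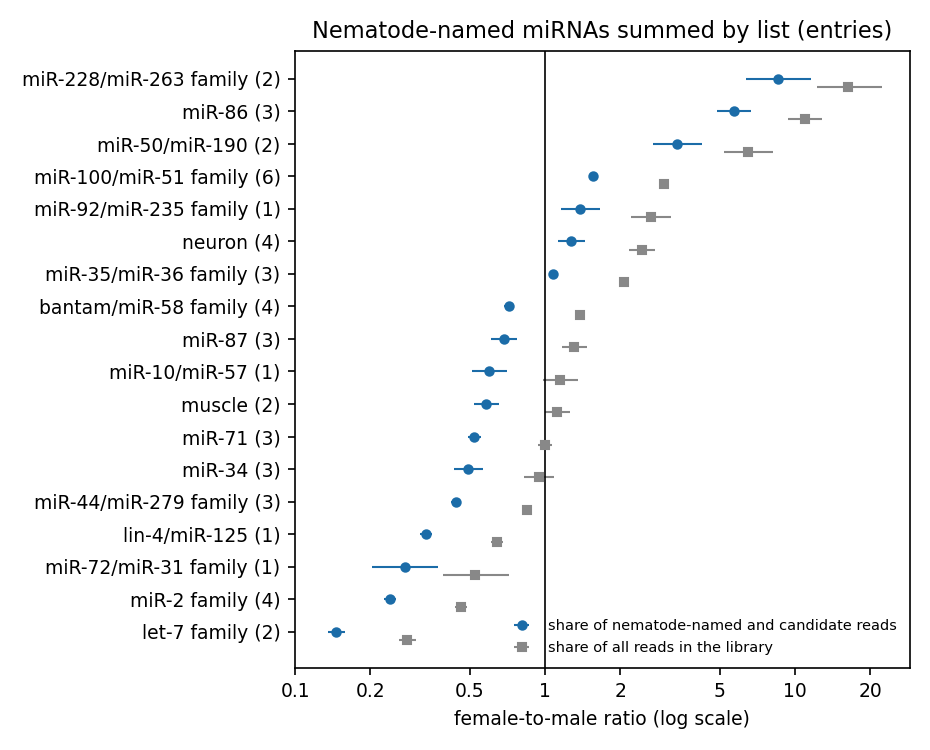
Female-to-male ratio (log scale) of nematode-named miRNAs summed by list, with the number of entries in brackets, as share of all reads (squares) and of nematode-named plus candidate reads (circles), with 95% counting intervals. The miR-228, miR-86 and miR-50 lists lie highest and the let-7 family lowest on both scales, 16.4 and 0.281 over all reads, and on the authors' normalized values the squares move 4.67-fold to the right, which puts each list on the female side.

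Most mammal-named miRNAs were higher in the male library, and a group of epithelial miRNAs was not. Among others on the female side was miR-146b, chosen after its values were seen, with 329 female and 18 male reads over its 2 entries. Among the most abundant, cgr-miR-143_R+1, a smooth muscle and fibroblast miRNA, was 8.92-fold higher in the male library (8.16 to 9.75) and ocu-miR-125b-5p 10.1-fold higher. At low counts, mmu-miR-5119_R-1_1ss5TA (61 male and 6 female reads) was 39.7-fold higher in the male, and miR-221-5p, with 32 male and 5 female reads over its 2 entries, was higher by 9.68-fold to 82.3-fold (95% interval). The entries ocu-let-7a-5p_R+1_1ss9TG and ocu-miR-24-2-5p_1ss3AG were at 0 in the female library. Against the floor they were 27.4-fold and 20.9-fold higher in the male (95% lower limits 20.4 and 15.1). The 2 entries of miR-28 were also at 0 in the female library, with 31 male reads, 40.4-fold higher against the floor (lower limit 30.9). In contrast, miR-205 (591 reads) and miR-203 (568 reads), both known from mammalian skin and other epithelia, were read in the female library and at 0 in the male. Against the floor they were 50.4-fold and 48.4-fold higher in the female (95% lower limits 40.9 and 39.3). The entry mmu-miR-2137_R-1_1ss16AG had 71 female and 0 male reads, 6.05-fold higher against the floor (95% lower limit 4.80).

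Of the 384 entries, 257 were read in both libraries, 70 in the female and 57 in the male library alone, with medians of 13 and 7 reads in the entries of a single library. With the female library thinned to the male total the order turned, with 63 in the female and 72.5 in the male library alone (medians of the draws). Nematode-named entries seen in a single library were mostly female (20 against 2), and mammal-named ones mostly male (52 against 32). With both libraries thinned to equal totals within each kind, an alternative chosen after seeing the data, these counts were 15 against 5 and 50 against 33. The top 10 entries held 71.6% of the female reads (71.4 to 71.7) and 43.1% of the male reads (42.7 to 43.5), with 5 entries shared, namely miR-100a, miR-100d, miR-36c, miR-81a and miR-279. Across the 287 eligible entries, which are not independent replicates, log2 shares had a Pearson r of 0.57 and a Spearman rho of 0.67. Within nematode-named and candidate entries these were 0.78 and 0.82, and within mammal-named entries 0.56 and 0.73.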

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

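The scale decided most counts; the worm-read scale, the limits to 1 kind of name and the alternatives to the mammal-named share were chosen after seeing the data. The 53 entries at least 2-fold higher in the female library became 119 with median-of-ratios scaling, 117 with TMM, 114 on the authors' values, 28 with at least 100 reads, 35 with intervals wholly beyond 2-fold and 9 when limited to worm entries and scaled to worm reads. The 178 higher in the male library became 36, 64 and 87 on the first 3 of these scales and 65 with at least 100 reads. Limited to worm entries they became 21, a fall that comes from leaving out the mammal-named entries. Scaling these worm entries to worm reads as well raised that count to 38. Over all 287 entries the worm-read scale alone gave 16 female and 197 male. The remaining alternatives stayed within 1.5 times of the main counts, as did the planned detection counts, although thinning made entries of the male library alone the more numerous. The Spearman correlation across entries was 0.395 with at least 100 reads, 0.817 within worm and 0.734 within mammal-named entries. The top 10 held 82.0% and 63.2% of female and male reads when summed by seed, and 76.7% and 70.8% of worm reads. Lists at least 2-fold higher in the female numbered 6, against 15 with median-of-ratios scaling and 3 for nematode-named entries on worm reads; lists higher in the male numbered 6, against 0 with median-of-ratios scaling. That scaling, which sets the median of entries seen in both libraries to no change and so follows the mammal-named majority, turned let-7 (log2 0.11), lin-4/miR-125 (0.95), miR-10/miR-57 (1.14), miR-2 (1.62) and miR-72/miR-31 (0.96) from at least 2-fold male to the female side, and miR-34 (2.30), miR-92/miR-235 (2.27) and miR-44/miR-279 (2.50) from within 2-fold. The mammal-named share of 6.71% and 51.4% was 5.10% and 38.2% on seeds that no worm entry carries, 6.04% and 48.8% at 21 nt or more, and 7.20% and 49.0% without the most abundant sequence of each library. Which scale is right was not tested. With 1 library per sex, no library could be left out and no paired analysis was possible because the 2 groups share no replicates. The read total over the deposited entries limits male values under 0.00401%.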

Other observations

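Further worm miRNAs, chosen after their values were seen, followed the female side. The nematode miRNAs bma-miR-5866 (4158 female and 318 male reads), bma-miR-5843_1ss11TC (3566 and 345) and asu-miR-5360-5p (1693 and 128) had female-to-male ratios of 3.34, 2.64 and 3.38 over all reads and 1.74, 1.38 and 1.76 over worm reads. For asu-miR-993-3p (1235 and 83 reads) the ratios were 3.81 and 1.98. On the male side, bma-miR-5364 (840 and 574 reads) was 2.67-fold higher in the male over all reads and 5.13-fold over worm reads, and bma-miR-236 (442 and 246 reads) 2.18-fold and 4.18-fold, although both turned to the female side on the authors' normalized values.

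Part of the predicted candidates share a seed with known worm miRNAs, which alone does not make them close relatives. Of 41 candidate sequences, 11 carry the seed of a nematode-named entry, and these hold 61.5% of the female and 64.3% of the male candidate reads. PC-3p-65_3608 shares its first 21 nt with miR-36c, the whole length of that entry, and its ratio of 2.04 (1.87 to 2.23) is near the 2.01 of miR-36c. PC-3p-1163_341 likewise shares its first 22 nt with miR-2c, with ratios of 0.498 and 0.483. PC-3p-281_1188 (2825.5 female and 437 male reads) carries the miR-2 seed and PC-3p-100_2763 (2267 and 792 reads) that of the bantam family. Their ratios were 1.65 and 0.732 over all reads and 0.861 and 0.381 over worm reads.

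Of the lists of mammalian miRNAs written after the table was seen, miRNAs of fibroblasts and smooth muscle (miR-21, miR-143, miR-145, miR-199 and miR-214, of which miR-21 and miR-143 are also on the list fixed in advance) held 1.81% of female and 19.1% of male reads, 10.6-fold higher in the male library (10.2 to 10.9). Of the 5287 female and 14274 male reads of this list, 3156 and 8346 were on 2 entries of miR-21. The miR-302 cluster, known from pluripotent and early embryonic cells, was present in both libraries with 341 and 649.3 reads, 7.44-fold higher in the male (6.52 to 8.51). Blood cell miRNAs were sparse, 111 and 131 reads, and split: miR-486 (52 and 107) and miR-155 (11 and 17) held most male reads, while miR-142-3p (18 and 0), miR-150 (10 and 0) and miR-142-5p (20 and 7) had more female reads. Epithelial miRNAs (miR-203, miR-205, miR-200a, miR-200b and miR-429) had 1388 female and 0 male reads, 118-fold higher in the female against the floor. The 95% upper limit of their male-to-female ratio was 0.0104.

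The seed test and the hairpin test below were set out before their results were seen, and the other tests only after. The seed test went against conserved worm sequences under mammalian names as the source of the larger mammal-named share of the male library. Of the male mammal-named reads, 74.2% lie on seeds that no nematode-named or candidate entry carries, and of the female ones 76.0%. Seeds were compared only among the deposited entries, so worm miRNAs that stand only under mammalian names could not be excluded. A single mammalian source of like profile does not account for all 64 abundant mammal-named sequences. The 3 epithelial ones, miR-205, miR-203 and miR-200b, had 591, 568 and 126 female and 0 male reads. Whether such a source lies behind the other 61 stays open. A male-to-female read ratio within 2-fold of the median of 2.28 was seen in 56 of 64 (87.5%), and in 56 of 61 (91.8%) without the epithelial ones. These lie on either side of a 90% bar that was set after the data were seen. The other 5 outside include bta-miR-146b (329 female and 18 male reads) and age-miR-214_R+1 (54 and 261). Whether the male culture released less worm RNA over a like mammalian background or held more mammalian RNA cannot be told apart, since worm reads were 48.6% of the male and 93.3% of the female library and no blank medium or input amount was analysed here. A difference between the sexes stays open as well and was not tested.

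A shared source of like profile does not account for the epithelial miRNAs, none of which stands on another of the lists. Since their list was written after the table was seen, the comparison describes these miRNAs and is no independent test. At the median male-to-female read ratio of abundant mammal-named sequences, 2.28, their 1388 female reads would go with 3162 reads in the male library, where 0 were seen. A candidate explanation is a further mammalian source in the female sample. Such a source need not be epithelial cells alone, since miR-146b was also higher in the female by share, with 329 female and 18 male reads. A source in handling or library making and a source in the culture cannot be separated with 1 library per sex, and no biological explanation was tested.

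The male-high candidates PC-5p-8384_52 (138 male and 5 female reads) and PC-3p-32855_9 (14 and 0) may be the arms of a hairpin. Their predicted duplex energy was -18.1 kcal/mol, the lowest of PC-5p-8384_52 with any of 27 candidate 3p sequences, the next being -14.2 kcal/mol. Without a genome the hairpin itself was not examined, and the duplex does not say why both arms were read mainly in the male library.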
